A study of Mus musculus with 25 samples.

How the data were processed

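Liver polyA RNA was sequenced from 25 samples of male C57BL6/J mice at 24 months of age, in 4 groups that cross genotype (Rosa26KO or p53KO) with diet (control diet or high-fat diet, HFD). The groups held 6 samples (Control_Rosa26KO), 6 samples (HFD_Rosa26KO), 6 samples (Control_p53KO) and 7 samples (HFD_p53KO). The labels describe flash-frozen tissue, column RNA extraction and paired reads of 75 bases, and they do not state how the knockouts were made. Each library was treated as a separate sample. The p-values therefore measure the spread between these samples.

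The values are raw read counts per gene, deposited as 1 table of 24537 genes, with gene symbols per the file headers. Per the submitters' processing notes the reads were aligned with STAR to GRCm38/mm10 and counted with HOMER. The versions, the strand of counting, the gene annotation and the handling of reads that match several places are not given in the sources used here. Counts of genes with close paralogs or with exons that overlap another gene can therefore include reads of the neighbour. Positions are from GENCODE M21 on GRCm38. Of the 24537 symbols, 23828 were matched in a table of gene names.

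Genes were kept by filterByExpr in edgeR 4.0.16 with a minimum count of 10 and a minimum total of 15, which left 14133 genes. Libraries were scaled by TMM. A quasi-likelihood negative binomial model with robust dispersion was fitted in edgeR to all 25 libraries with 1 mean per group, and two-sided p-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The 6 comparisons were p53KO against Rosa26KO on control diet, the same on HFD, the average of both, HFD against control diet in Rosa26KO, the same in p53KO, and the interaction, coded as the HFD effect in p53KO minus that in Rosa26KO. Trp53, Cdkn1a and Mdm2 were also tested with two-sided exact permutation tests of the normalised counts (CPM, scaled to library size), permuted within diet for the average. For these genes the test fixed before the data were examined was edgeR between genotypes. The exact p-values were not adjusted for the number of tests. CPM values are given as mean ± SD.

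Sets of genes were fixed before the data were examined, as were the comparisons, the tests other than exact permutation and the rule for naming genes. These 34 lists covered p53 targets, lipid, hepatocyte, immune and other liver programmes. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 3 and a preset correlation between genes of 0.01, adjusted over the 34 lists of a comparison. Camera was repeated with a correlation estimated from the data, and fry and exact permutation of list scores (the mean log2 CPM of the members) were run beside it. Counts of list members past the threshold are given over all genes and adjusted over the list alone.

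Genes are named by rule. Trp53, Cdkn1a and Mdm2 are always named. In each comparison, among genes past the threshold with a mean of at least 1 CPM, the 5 largest rises and falls and the 5 rises and falls of smallest p were eligible, with model and clone names passed over. Up to 4 members of smallest p were eligible from each list with a camera call or with at least 3 members past the threshold, and a member past the threshold from another list could be named. Where fewer than 10 genes passed, the 10 of smallest p were eligible. Some eligible genes are not reported here, while the counts include them.

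Alternatives covered RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom with sample quality weights, dispersion without the robust option, a term for the replicate number, a fit to the compared groups only, and each library left out in turn. Settings added later were a term for runs of library names, libraries high in neutrophil or in acute phase genes left out, surrogate variables (sva 3.50.0), a trended variance in camera, exact permutation of list scores, and values of the named genes, of list scores and of the exact tests of Trp53, Cdkn1a and Mdm2 with libraries left out. Principal components used the 1000 most variable genes in log2 CPM with a prior count of 2. For each comparison 100 splits of the samples, the real one included, were fitted in the same way. The procedure was tested on simulated data with 200 changed genes. The statistical work used R 4.3.3, and summaries and plots used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. No library was left out of the reported values.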

Results

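Gene expression was measured by RNA sequencing in livers of male mice aged 24 months that carried a p53 knockout (p53KO) or a control knockout of the Rosa26 locus (Rosa26KO), on control diet or HFD. The 4 groups were Control_Rosa26KO (n = 6), HFD_Rosa26KO (n = 6), Control_p53KO (n = 6) and HFD_p53KO (n = 7). Total counts per library ran from 16324283 to 21501281. The group means were 20006419 in Control_Rosa26KO, 19419406 in HFD_Rosa26KO, 19420727 in Control_p53KO and 19391513 in HFD_p53KO. Of 24537 genes in the table, 14133 had enough counts to be tested. In simulated data of this depth and size with 200 changed genes, 44.8% (p53KO against Rosa26KO on HFD) to 58.2% (HFD against control diet in p53KO) of genes with a 1.5-fold change were recovered, and 90.9% to 95.5% of those with a 4-fold change. Each gene was simulated on its own, with no outlying library and no joint movement of genes. Recovery in the real data may therefore be lower.

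The first principal component held 37.7% of the variance of the most variable genes, and the next ones 18.8%, 9.70% and 6.07%. On the first component Control_Rosa26KO lay at -18.6 ± 18.6 (SD, n = 6), HFD_Rosa26KO at 14.2 ± 6.20 (SD, n = 6), Control_p53KO at -6.02 ± 25.8 (SD, n = 6) and HFD_p53KO at 8.97 ± 24.0 (SD, n = 7). The spread within both p53KO groups was larger than the distance between their means. HFD_p53KO 7 (-31.2) and HFD_p53KO 5 (-15.1) lay on the side of the control-diet mean, while Control_p53KO 1 (23.4), Control_p53KO 3 (25.8) and Control_Rosa26KO 2 (15.4) lay on the side of HFD. Neutrophil marker scores were high in Control_p53KO 1 (4.41 above the mean of all libraries on the log2 scale), HFD_Rosa26KO 6 (3.51) and Control_p53KO 3 (2.21). Acute phase scores were high in Control_p53KO 1 (2.46), Control_Rosa26KO 1 (2.03), HFD_p53KO 2 (1.74) and HFD_p53KO 7 (1.23).

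Whether the knockout lowered its own transcript was asked of Trp53 (chromosome 11, 69580359 to 69591873, GRCm38), which encodes p53, and of its classical targets Cdkn1a (chromosome 17, 29090976 to 29100727), a cell cycle inhibitor, and Mdm2 (chromosome 10, 117688875 to 117710758), the ligase that degrades p53. Trp53 was at 36.8 ± 4.80 CPM (SD, n = 6) in Control_Rosa26KO and 24.1 ± 6.89 CPM (SD, n = 6) in Control_p53KO, a fall of -34.5% by the fitted fold change. On HFD it was at 37.1 ± 4.56 CPM (SD, n = 6) in Rosa26KO and 26.1 ± 4.47 CPM (SD, n = 7) in p53KO, a fall of -29.9%. The two-sided exact permutation p was 0.00866 on control diet, 0.00117 on HFD and 2.33e-05 for both diets together. This exact test was not among the tests fixed before the data were examined. Across all genes the adjusted p of Trp53 in the reported edgeR fit stayed above the threshold. It was 0.453 on control diet, 0.9998 on HFD and 0.210 for the average (log2 fold change -0.56, SE 0.10). About this average, DESeq2 gave Trp53 an adjusted p of 0.00314 and limma voom 0.00301. A fit with the replicate number as a term gave 0.0299 for the average. With surrogate variables, a setting added later, the adjusted p was 7.47e-05 for the average and 0.000777 on control diet. Control_p53KO 3 (35.6 CPM) lay within the Rosa26KO range on control diet, 31.6 to 43.7 CPM, and HFD_p53KO 7 (31.05 CPM) lay within that on HFD, 30.6 to 43.8 CPM. Without Control_p53KO 3 the average reached an adjusted p of 0.00634 (log2 fold change -0.63). A transcript count does not measure p53 protein.

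Cdkn1a was at 35.8 ± 27.4 CPM (SD, n = 6) in Control_Rosa26KO, 56.3 ± 22.8 (SD, n = 6) in HFD_Rosa26KO, 13.5 ± 9.40 (SD, n = 6) in Control_p53KO and 43.1 ± 29.1 (SD, n = 7) in HFD_p53KO. It was lower in p53KO on control diet by an exact permutation test (log2 fold change -1.41, SE 0.54, two-sided exact p 0.0390, edgeR adjusted p 0.472), and not by that test on HFD (log2 fold change -0.38, exact p 0.384). The result on control diet leaned on Control_Rosa26KO 2 (88.9 CPM): without it the group mean was 25.2 CPM, the log2 fold change -0.90 and the exact p 0.0801. The exact test passed in 5 of 12 tests with 1 library left out, and also missed the threshold without Control_Rosa26KO 1 (0.0584) or 3 (0.0541), or without Control_p53KO 2 (0.0974), 4 (0.0801), 5 (0.0996) or 6 (0.0714). Mdm2 was at 33.9 ± 2.52 CPM (SD, n = 6), 37.8 ± 4.5 (SD, n = 6), 31.1 ± 2.02 (SD, n = 6) and 37.3 ± 3.71 (SD, n = 7) in the same order. Between genotypes on control diet Mdm2 had a log2 fold change of -0.12 and an exact p of 0.0714. Between diets in p53KO, Cdkn1a (log2 fold change 1.68, SE 0.53, exact p 0.0274) and Mdm2 (log2 fold change 0.26, exact p 0.00583) were higher on HFD by the exact test, with edgeR adjusted p of 0.0796 and 0.0685 across all genes. The exact p-values of this paragraph were not adjusted for the number of genes and comparisons tested. With 1 library left out the exact test of Mdm2 passed in 13 of 13 tests and that of Cdkn1a in 9 of 13, the exceptions being Control_p53KO 2 (exact p 0.0669), 4 (0.0593), 5 (0.0669) and 6 (0.0505). In edgeR Cdkn1a passed without HFD_p53KO 5 (adjusted p 0.0401) and Mdm2 without Control_p53KO 4 (adjusted p 0.0456). In each group but Control_p53KO the 2 highest Cdkn1a values lay in replicates 1 and 2, seen after the tests. In HFD_p53KO these were 89.7 and 74.4 CPM, against 7.52 to 40.5 CPM in its other libraries. In Control_p53KO the highest was replicate 3 (25.6 CPM). The exact tests were not permuted within runs of library names, and Cdkn1a was not tested between runs.

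**Figure D1:**
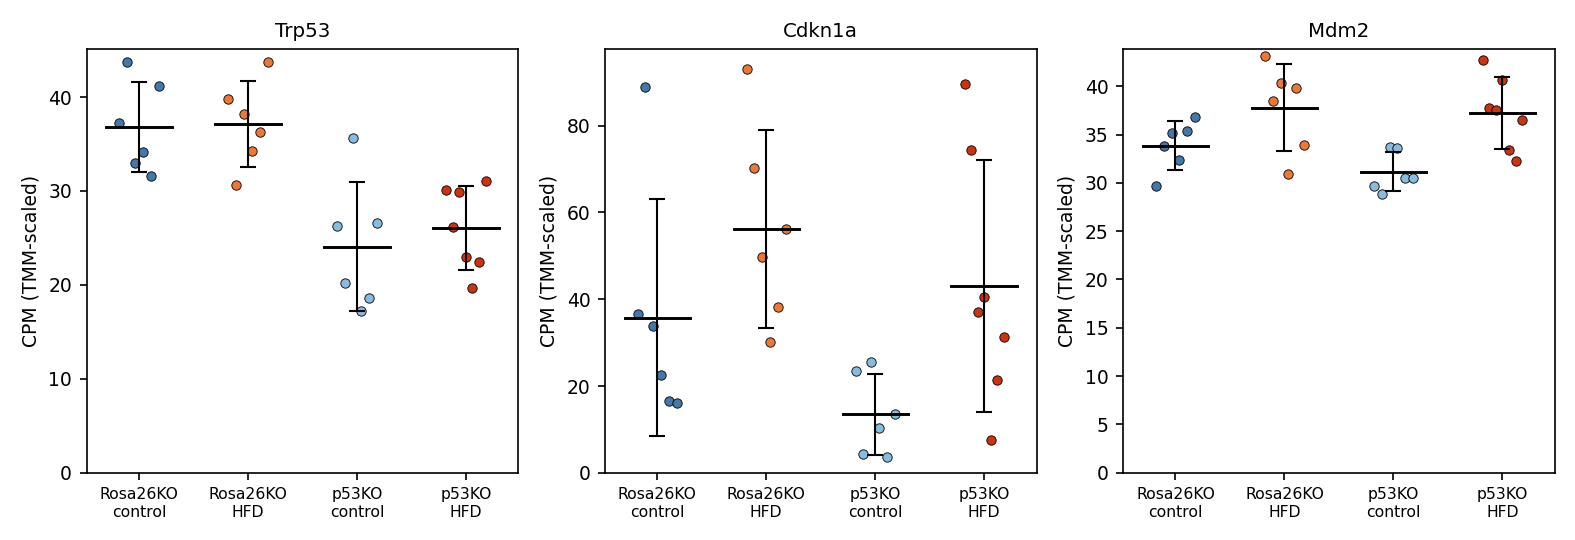
Normalised counts (CPM) of Trp53, Cdkn1a and Mdm2 in each library of the 4 groups, with a line at the group mean and bars of 1 SD (n = 6, 6, 6 and 7). Trp53 lay lower in both p53KO groups than in both Rosa26KO groups, with Control_p53KO 3 at 35.6 CPM.

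What the knockout changed in livers of mice on control diet was asked by p53KO against Rosa26KO at that diet. The amino acid transporter-like gene Slc7a4 fell from 2.92 ± 0.397 CPM (SD, n = 6) to 1.38 ± 0.390 CPM (SD, n = 6) by DESeq2 (log2 fold change -1.08, adjusted p 0.00193), with no overlap between the libraries of the groups. In edgeR its adjusted p was 0.337 and it did not pass. Its exons overlap P2rx6, and the strand of counting is not stated. The p53 targets Eda2r (log2 fold change -1.89), a receptor of the tumour necrosis factor family, Trp53cor1 (-1.77), a noncoding RNA, and Aen (-0.57), a nuclease of apoptosis, were lower in p53KO without passing (edgeR adjusted p 0.453 for each). Sult1e1, an estrogen sulfotransferase, had a log2 fold change of 6.51 that came from Control_p53KO 1 alone, at 112.8 CPM.

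By edgeR 0 of 14133 genes passed on control diet, and 1408 had an unadjusted p under 0.05. Uniform p-values would give 707, while other splits of the same libraries gave a median of 962 and 22 of 100 splits, the real one included, gave at least 1408. DESeq2 called 1 gene (Slc7a4) with 1542 at an unadjusted p under 0.05, and limma voom called 0 with 805. The smallest edgeR p-values also belonged to Fzr1 (-0.33), whose exons overlap Mfsd12, Hdac4 (0.35), Commd3 (-0.34), Fam110a (-0.71), Pdcd10 (0.26), Atp8b5 (-1.65), Dpy30 (-0.34) and Rogdi (-0.39), given as log2 fold changes, each with an adjusted p of 0.453.

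Of the fixed lists on control diet, camera placed 6 higher and 9 lower in p53KO. The p53 target genes were lower (median log2 fold change -0.19, 32 of 43 members below 0, adjusted p 0.000242), as were the fatty acid synthesis genes (median -0.39, 21 of 21 below 0, 5.77e-07) and the oxidative phosphorylation genes (median -0.16, 34 of 34 below 0, 2.42e-05). The neutrophil markers (median 3.25, 0.000200), T and NK cell markers (0.85, 0.000358), cell cycle genes (0.36, 0.000358), Kupffer cell markers (0.72, 0.0136), monocyte and lipid-associated macrophage markers (0.66, 0.0294) and oncofetal genes (0.52, 0.0169) were higher. Cholesterol synthesis (-0.14, 0.0190), lipid droplet (-0.15, 0.0330), fatty acid oxidation (-0.21, 0.00119), xenobiotic metabolism (-0.19, 0.00478), male-biased (-0.29, 0.0169) and pericentral genes (-0.21, 0.00645) were lower. With an estimated correlation no call held (adjusted p 0.776 for each). Over all genes 0 members passed by edgeR, and adjusted over the list alone 2 p53 targets were lower and 9 neutrophil markers, 2 oncofetal genes and 1 macrophage marker were higher. Single libraries moved most of these lists, as measured by the difference of list scores. Of the 15 lists, 2 (fatty acid synthesis and pericentral genes) moved by less than 1.5 times whichever single library was left out. Without Control_p53KO 3 the difference went from 0.54 to 0.21 for T and NK cell markers, from 0.38 to 0.10 for Kupffer cell markers, from 0.37 to 0.10 for macrophage markers, from 0.43 to 0.16 for cell cycle genes, from -0.19 to -0.03 for cholesterol synthesis, from -0.30 to -0.19 for xenobiotic metabolism and from -0.17 to -0.10 for oxidative phosphorylation. Without Control_p53KO 1 it went from 1.42 to 0.67 for neutrophil markers, from 0.49 to 0.17 for oncofetal genes, from -0.58 to -0.08 for male-biased genes, from -0.27 to -0.12 for lipid droplet genes, and to -0.05 for fatty acid oxidation, 0.26 for cell cycle and 0.20 for macrophage genes. Without Control_Rosa26KO 2 it went from -0.24 to -0.14 for the p53 target genes and to 0.76 for cell cycle genes. Without Control_Rosa26KO 5 it was 0.12 for Kupffer, 0.16 for macrophage, 0.26 for cell cycle, -0.17 for lipid droplet, -0.11 for fatty acid oxidation and -0.11 for oxidative phosphorylation genes. Larger differences came without Control_p53KO 4 (-0.44 for lipid droplet, -0.45 for fatty acid oxidation, -0.48 for xenobiotic, -0.25 for oxidative phosphorylation and 0.60 for macrophage genes), Control_Rosa26KO 1 (-0.41 for lipid droplet and -0.43 for fatty acid oxidation genes), Control_p53KO 5 (0.69 for cell cycle genes) and Control_p53KO 2 (-0.28 for cholesterol synthesis). Smaller ones came without Control_Rosa26KO 4 (-0.10 for cholesterol synthesis) and Control_Rosa26KO 3 (-0.11 for oxidative phosphorylation). Without both Control_p53KO 1 and 3, the libraries high in neutrophil markers here, every one of the 15 lists but the p53 target genes (-0.34) moved by more than 1.5 times. The difference reversed for cell cycle (-0.11), macrophage (-0.18), fatty acid oxidation (0.04) and male-biased genes (0.03), and shrank to 0.0998 for neutrophil, 0.08 for Kupffer, 0.08 for T and NK cell and 0.06 for oncofetal genes, -0.06 for xenobiotic, -0.03 for oxidative phosphorylation, -0.12 for lipid droplet, -0.0956 for cholesterol synthesis, -0.19 for fatty acid synthesis (-0.54 with all) and -0.105 for pericentral genes (-0.23 with all).

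What the knockout changed under HFD was asked by p53KO against Rosa26KO within HFD. By edgeR no gene separated the genotypes. The platelet chemokine gene Ppbp was at 24.6 ± 51.9 CPM (SD, n = 6) in Rosa26KO and 1.61 ± 0.898 CPM (SD, n = 7) in p53KO (log2 fold change -3.93), but HFD_Rosa26KO 6 alone held 130.2 CPM. Stab2, a scavenger receptor of sinusoidal endothelium, was at 83.9 ± 42.0 CPM (SD, n = 6) against 49.5 ± 14.5 CPM (SD, n = 7), with a log2 fold change of -0.76. The endothelial receptor gene Tek (-0.67) and the stellate cell gene Reln (-0.70) also had negative log2 fold changes, all with an edgeR adjusted p of 0.9998. The count was 0 of 14133 by edgeR, with 509 at an unadjusted p under 0.05. Other splits of these libraries gave a median of 338, and 33 of 100 gave at least 509. DESeq2 called 1 gene (Ppbp, adjusted p 0.0249) with 558 at an unadjusted p under 0.05, and limma voom called 0 with 1171. The genes of smallest p also held Sptb (-2.12), whose exons overlap Plekhg3, Zfp691 (0.33), Cyp2d12 (1.04), Gp1ba (-3.07), Egln1 (-0.31), Colec10 (-0.85), Tubb1 (-3.02), Ttyh1 (-1.04), whose exons overlap a noncoding gene, and Zfp746 (0.31).

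Under HFD camera placed 2 lists higher and 13 lower in p53KO. Interferon-stimulated genes (median log2 fold change 0.33, 37 of 38 above 0, adjusted p 6.17e-07) and male-biased liver genes (0.37, 0.000301) were higher. The sinusoidal endothelial markers (median -0.43, 19 of 19 below 0, 9.40e-14) and hepatic stellate cell markers (-0.35, 14 of 14 below 0, 3.07e-09) were lower. So were the p53 target genes (-0.07, 29 of 43 below 0, 0.00190), cell cycle genes (-0.15, 8.97e-06), fatty acid synthesis genes (-0.37, 0.000126), gluconeogenesis genes (-0.14, 0.00445), female-biased genes (-0.53, 0.00190), extracellular matrix genes (-0.11, 0.000174), Kupffer cell markers (-0.32, 0.00172), neutrophil markers (-1.60, 0.000467), erythroid markers (-1.23, 4.89e-05), periportal genes (-0.28, 9.99e-05) and oxidative phosphorylation genes (-0.06, 0.0234). No call held with an estimated correlation, where the smallest adjusted p was 0.546. Adjusted over the list alone, 4 stellate, 3 neutrophil and 3 erythroid markers were lower, against 0 over all genes by edgeR. Of the 15 lists, 3 (interferon-stimulated, gluconeogenesis and periportal genes) moved in list score by less than 1.5 times whichever single library was left out. Without HFD_p53KO 7 the score difference went from -0.43 to -0.23 for stellate markers, from -0.46 to -0.29 for endothelial markers, from 0.53 to 0.23 for male-biased genes, from -0.56 to -0.27 for female-biased genes, from -0.30 to -0.04 for extracellular matrix genes and from -0.41 to -0.21 for cell cycle genes. Without HFD_p53KO 5 it was -0.14 for p53 target genes (-0.21 with all libraries), -0.25 for cell cycle and -0.20 for matrix genes. Without HFD_Rosa26KO 6 it went from -1.17 to -0.61 for neutrophil, from -0.86 to -0.39 for erythroid and from -0.34 to -0.19 for Kupffer markers. It was -0.55 for erythroid markers without HFD_Rosa26KO 1, 0.35 for male-biased genes without HFD_Rosa26KO 5, and -0.21 for fatty acid synthesis without HFD_p53KO 2 or HFD_Rosa26KO 3 (-0.33 with all). For oxidative phosphorylation (-0.07 with all) 7 libraries moved it by more than 1.5 times, from -0.11 without HFD_Rosa26KO 6 to 0.003 without HFD_Rosa26KO 4.

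The genotype effect over both diets was asked by their average, which used all 25 libraries. Trp53 had the smallest p of all genes. The phospholipid flippase gene Atp8b5 (log2 fold change -1.28, SE 0.26) was lower, and the repressor of oxidative stress genes Bach1 (0.31, SE 0.06) and the zinc finger gene Zfp691 (0.28, SE 0.06) were higher in p53KO, each with an edgeR adjusted p of 0.219. By DESeq2 all of them passed, with adjusted p of 0.0123 for Atp8b5, 0.0129 for Bach1 and 0.0270 for Zfp691. Bach1 was at 31.7 ± 4.64 CPM (SD, n = 6) in Control_Rosa26KO, 39.3 ± 4.08 (SD, n = 6) in Control_p53KO, 30.9 ± 2.84 (SD, n = 6) in HFD_Rosa26KO and 38.1 ± 3.001 (SD, n = 7) in HFD_p53KO. The p53 targets Eda2r (-1.33), Trp53cor1 (-1.20), Aen (-0.43) and Bax (-0.29) and the lipid genes Srebf1 (-0.40), whose exons overlap Rai1, and Pnpla3 (-1.25) had negative log2 fold changes and did not pass in edgeR.

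By edgeR the average called 0 genes, with 573 at an unadjusted p under 0.05, where other splits gave a median of 653. DESeq2 called 7 (639 unadjusted), which were Trp53, Atp8b5, Bach1, Zfp691, Eda2r, Commd3 and Rpph1, whose exons overlap Ccnb1ip1. Limma voom called 2 (972 unadjusted), which were Trp53 and Endog (log2 fold change -0.52, adjusted p 0.0217), and Endog, whose exons overlap Spout1, was chosen after its values were seen. Ino80 (0.19) and Hdac4 (0.22) were also among the 10 genes of smallest p. Without Control_p53KO 3 edgeR called 1 gene, Trp53.

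Camera placed 3 lists higher and 9 lower for the average. The p53 target genes (median log2 fold change -0.14, 32 of 43 below 0, adjusted p 7.01e-08, with an estimated correlation 0.429) and the fatty acid synthesis genes (-0.39, 21 of 21 below 0, 4.32e-13, with an estimated correlation 0.448) were lower. By exact permutation of list scores their two-sided p was 0.0250 and 0.0349, adjusted over the lists to 0.593 for both. Oxidative phosphorylation (-0.11, 34 of 34 below 0, 4.32e-08), sinusoidal endothelial (-0.20, 3.53e-06), stellate (-0.18, 4.01e-05), periportal (-0.15, 0.000379), fatty acid oxidation (-0.10, 0.00171), lipid droplet (-0.11, 0.0373) and erythroid (-0.39, 0.0373) genes were also lower. T and NK cell markers (0.59, 0.000379), interferon-stimulated genes (0.16, 0.0162) and oncofetal genes (0.26, 0.0354) were higher. With an estimated correlation no call held. Adjusted over the list alone, 4 p53 targets were lower and 1 oncofetal gene was higher, against 0 over all genes by edgeR. The score differences of the p53 target, fatty acid synthesis and oxidative phosphorylation genes moved by less than 1.5 times whichever single library was left out. Others rested on single libraries: T and NK cell markers went from 0.28 to 0.11 and periportal genes from -0.23 to -0.14 without Control_p53KO 3, oncofetal genes from 0.24 to 0.08, lipid droplet genes from -0.17 to -0.09 and fatty acid oxidation genes from -0.18 to -0.08 without Control_p53KO 1, and endothelial markers from -0.21 to -0.12, stellate markers from -0.21 to -0.11 and lipid droplet genes to -0.10 without HFD_p53KO 7. Erythroid markers went from -0.30 to -0.06 without HFD_Rosa26KO 6 and to -0.14 without HFD_Rosa26KO 1. Lipid droplet genes were at -0.25 without Control_p53KO 4 and -0.26 without HFD_Rosa26KO 6, and fatty acid oxidation genes at -0.28 without Control_p53KO 4 and -0.11 without Control_Rosa26KO 5. For interferon-stimulated genes (0.11) 11 libraries moved it by more than 1.5 times, from 0.02 without Control_p53KO 4 to 0.24 without Control_Rosa26KO 2. Without Control_p53KO 1 and 3 and HFD_Rosa26KO 6 together, T and NK cell markers were at 0.03, oncofetal genes at 0.02, fatty acid oxidation genes at -0.09, periportal genes at -0.14 and oxidative phosphorylation genes at -0.07 (-0.12 with all).

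The effect of HFD in mice with intact Trp53 was asked by HFD against control diet in Rosa26KO. Plin4 (chromosome 17, 56100591 to 56109803), which coats lipid droplets, rose from 15.3 ± 4.42 CPM (SD, n = 6) to 84.2 ± 26.9 CPM (SD, n = 6), with a log2 fold change of 2.46 (SE 0.33, edgeR adjusted p 0.000897). Genes of cholesterol synthesis fell: Pmvk (chromosome 3, 89454541 to 89469013) went from 98.5 ± 21.1 to 33.3 ± 8.98 CPM (SD, n = 6 each; log2 fold change -1.57, SE 0.26, adjusted p 0.00354), and Fdps fell as well (-1.45, adjusted p 0.0174). Acss2, which makes acetyl-CoA for lipid synthesis, fell from 586.5 ± 151.1 to 154.3 ± 44.2 CPM (SD, n = 6 each; log2 fold change -1.93, adjusted p 0.00579); its exons overlap Ggt7 and Gss. The carboxylesterase gene Ces2a (chromosome 8, 104734003 to 104741634), which has close paralogs, had the smallest p, falling from 350.0 ± 56.8 to 85.9 ± 18.7 CPM (SD, n = 6 each; log2 fold change -2.03, SE 0.24, adjusted p 0.000242). In Plin4, Pmvk, Fdps, Acss2 and Ces2a every HFD library lay on the same side of every control library.

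Further rises in Rosa26KO were those of Fam107b (0.99, chromosome 2, 3570488 to 3782142), the recombination gene Rad51b (2.84), the phosphatase Dusp3 (0.53), the deiodinase Dio1 (2.46) and the female-biased cytochrome Cyp2b13 (5.55), whose reads can be shared with Cyp2b paralogs. Further falls were those of Gm2a (-0.82, chromosome 11, 55098115 to 55113029), a lysosomal lipid carrier, Epb41l5 (-0.60), Pdzk1ip1 (-1.54), Slc13a2 (-2.75), whose exons overlap an antisense gene, Adgrf1 (-2.60), the drug-inducible cytochrome Cyp2b10 (-3.37), Clec2h (-2.84) and Nat8f7 (-4.27), one of a paralog family. Values are log2 fold changes. The platelet genes Ppbp (4.32) and Tubb1 (3.89) passed, but HFD_Rosa26KO 6 carried their size: without it they had log2 fold changes of 1.48 and 1.86 and adjusted p of 0.188 and 0.113. Their calls stood in 7 and 6 of 12 fits with 1 library left out. The red cell gene Slc4a1 (4.94) kept a log2 fold change of 4.02 without that library, but its call stood in only 2 of 12 fits with 1 library left out (largest adjusted p 0.108).

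HFD moved 213 genes in Rosa26KO by edgeR, 63 up and 150 down, with 2467 at an unadjusted p under 0.05. DESeq2 called 615 and limma voom 3038, and these held 213 and 209 of the same genes. Leaving out single libraries moved the count between 93 and 509. It was 120 without Control_Rosa26KO 1, 509 without Control_Rosa26KO 2, 93 without Control_Rosa26KO 4, 97 without Control_Rosa26KO 5, 96 without HFD_Rosa26KO 1, 95 without HFD_Rosa26KO 2, 94 without HFD_Rosa26KO 3 and 98 without HFD_Rosa26KO 5. Libraries outside the comparison also moved it, to 372 without Control_p53KO 3 and to 395 without HFD_p53KO 7. Of 35 genes eligible for naming and past the threshold here, all kept their direction and 18 passed in each of 12 fits with 1 library left out, among them Plin4, Pmvk, Acss2, Ces2a, Fam107b and Gm2a, while Fdps passed in 11 of the 12, Acacb and Nat8f7 in 8, Cyp1a2 and Tm7sf2 in 7, Clec2h and Cyp4a12b in 5, Slc22a27 in 4, Abcb4, Acat2, Herc6, Mlxipl and Slc25a1 in 3 and Atf4 (log2 fold change -0.39) in 1.

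Camera placed 11 lists higher and 6 lower on HFD in Rosa26KO. Cholesterol synthesis genes were lower (median log2 fold change -0.90, 25 of 25 below 0, adjusted p 1.48e-17, with an estimated correlation 0.616), and 5 of 25 passed over all genes, among them Pmvk, Fdps, Acat2 (-0.83) and Tm7sf2 (-1.25), whose exons overlap Vps51, and 22 adjusted over the list alone. Fatty acid synthesis genes were lower (median -0.88, 20 of 21 below 0, 3.20e-09, with an estimated correlation 0.616), 5 over all genes, including Acss2, Acacb (-1.4), Mlxipl (-0.97) and Slc25a1 (-0.63), and 10 adjusted over the list alone. Lipid droplet genes were higher (0.87, 16 of 20 above 0, 0.000181, with an estimated correlation 0.616), 1 over all genes and 6 adjusted over the list alone. In this list Pparg had a log2 fold change of 0.89 and an adjusted p of 0.0529. Xenobiotic genes (-0.08, 0.00159) were lower, with 5 over all genes and 6 adjusted over the list alone, among them Gstm6 (-0.94) and Cyp1a2 (-1.44). Male-biased genes (-1.18, 17 of 18 below 0, 8.74e-07) were lower, with Cyp4a12b (-2.36) past the threshold and 5 adjusted over the list alone, and female-biased genes (1.17, 0.00456) were higher, with 2 over all genes (Cyp2b13 and Slc22a27) and 4 higher and 2 lower adjusted over the list alone. With an estimated correlation none of these calls held. The xenobiotic score difference went from -0.41 to -0.23 without HFD_Rosa26KO 6.

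Other lists higher on HFD in Rosa26KO were interferon-stimulated genes (median log2 fold change 0.68, 38 of 38 above 0, adjusted p 2.02e-12; Herc6 past the threshold at 0.90), cell cycle genes (0.70, 48 of 50 above 0, 2.02e-12), p53 target genes (0.29, 35 of 43 above 0, 0.000365), fatty acid oxidation genes (0.32, 27 of 30 above 0, 6.27e-05), extracellular matrix genes (0.41, 0.00132), Kupffer cell markers (0.42, 0.0299), macrophage markers (0.66, 0.00166), neutrophil markers (2.05, 0.00721) and erythroid markers (1.80, 0.000467). Bile acid genes (-0.24, 0.0498), with Abcb4 past the threshold at 0.70 against the direction of the list, and oxidative phosphorylation genes (-0.12, 0.00719) were lower. With an estimated correlation these adjusted p-values lay at 0.616 or above. Adjusted over the list alone, 8 erythroid markers, 3 neutrophil markers, 2 matrix genes and 1 each of the interferon-stimulated, p53 target, fatty acid oxidation and Kupffer genes were higher. Over all genes 2 erythroid markers passed. Of the 17 lists, 12 moved in list score by less than 1.5 times whichever single library was left out. Without HFD_Rosa26KO 6 the score difference went from 1.401 to 0.832 for neutrophil, from 1.37 to 0.89 for erythroid and from 0.32 to 0.17 for Kupffer markers and from -0.13 to -0.08 for oxidative phosphorylation. Without Control_Rosa26KO 5 it was 0.06 for Kupffer markers and -0.07 for oxidative phosphorylation, which was also at -0.07 without Control_Rosa26KO 3, -0.19 without Control_Rosa26KO 1 and -0.20 without HFD_Rosa26KO 4. In the macrophage list Fabp5 fell (-2.51) while the median was positive.

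**Figure D2:**
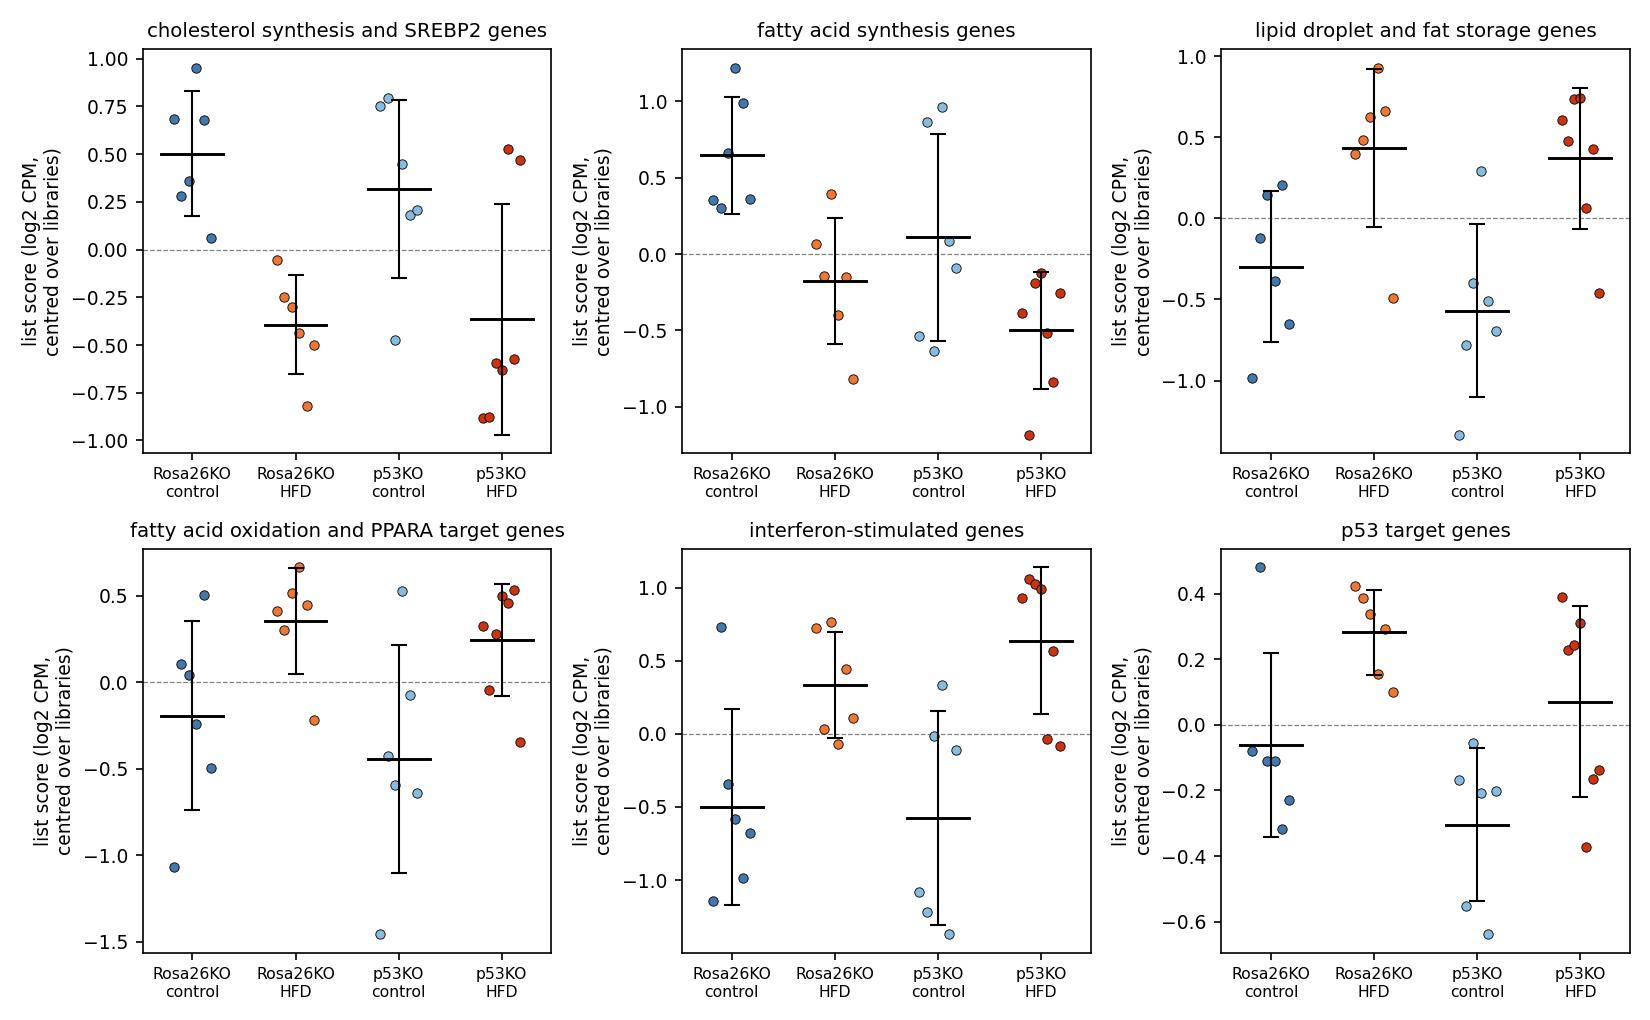
List scores (mean log2 CPM of the members, centred over the 25 libraries) of 6 gene lists in each library of the 4 groups, with the group mean and 1 SD. Cholesterol and fatty acid synthesis scores lay lower, and lipid droplet scores higher, on HFD in both genotypes.

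The effect of HFD in the knockout was asked by HFD against control diet in p53KO. Plin4 rose from 15.1 ± 7.15 CPM (SD, n = 6) to 68.0 ± 20.3 CPM (SD, n = 7), with a log2 fold change of 2.17 (SE 0.32, edgeR adjusted p 0.00139), and the droplet coat gene Plin2 (0.97, adjusted p 0.0177) and the lipid storage regulator Pparg (0.93, adjusted p 0.0280) rose too. The interferon-stimulated gene Herc6 (chromosome 6, 57581000 to 57664632) rose from 27.9 ± 10.2 to 56.7 ± 13.3 CPM (SD, n = 6 and 7; log2 fold change 1.02, SE 0.21, adjusted p 0.0113). Eda2r (X chromosome, 97333840 to 97377216) rose from 0.385 ± 0.264 to 2.18 ± 1.10 CPM (SD, n = 6 and 7; log2 fold change 2.47, SE 0.47, adjusted p 0.00845), and the p53 targets Sesn2 (0.78, adjusted p 0.0115), Ccng1 (0.53, adjusted p 0.0370) and Abhd4 (0.60, adjusted p 0.00845) rose with it. With 1 library left out Ccng1 passed in only 5 of 13 fits (largest adjusted p 0.0942). Gm2a had the smallest p, falling from 224.8 ± 22.4 to 123.3 ± 14.6 CPM (SD, n = 6 and 7; log2 fold change -0.87, SE 0.11, adjusted p 0.000999). In Plin4, Abhd4 and Gm2a every HFD library lay on the same side of every control library.

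Falls in p53KO also held Epb41l5 (-0.58), the fatty acid binding gene Fabp5 (-2.77), Adgrf1 (-3.75), Ces2a (-1.45), and Cyp3a41b, a paralog of Cyp3a41a, whose log2 fold change went from -3.04 to -1.33 (adjusted p 0.0477) without Control_p53KO 1. Rises also held Adora1 (1.24), whose exons overlap Mybph, Rogdi (0.59), the carnitine transporter gene Slc22a5 (0.68), Fam107b (0.80), Sprr1a (5.41), the carbonyl reductase gene Cbr3 (3.32), Spats2l (2.34) and Rad51b (2.29). Values are log2 fold changes. Control_p53KO 1 moved 3 further falls the most. Without it Sult1e1 (-4.98 with all libraries) had a log2 fold change of 1.4 and an adjusted p of 0.335, Cyp3a41a (-3.15) had -1.30 and 0.0502, and the insulin-repressed gene Igfbp1 (-2.05) had -1.38 and 0.136. The call of Cyp3a41a was lost only without that library, while those of Sult1e1 and Igfbp1 stood in 6 and 4 of 13 fits with 1 library left out. Cd207 (-5.04) was at 267.2 CPM in Control_p53KO 3, and without that library it still passed at -2.65 (adjusted p 0.0180).

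HFD moved 405 genes in p53KO by edgeR, 229 up and 176 down, with 2661 at an unadjusted p under 0.05. DESeq2 called 907 and limma voom 2189, which held 404 and 390 of the same genes. Leaving out single libraries moved the count between 173 and 760. It was 179 without Control_p53KO 2, 760 without Control_p53KO 4, 197 without Control_p53KO 5, 231 without Control_p53KO 6, 248 without HFD_p53KO 2, 244 without HFD_p53KO 3, 173 without HFD_p53KO 4 and 204 without HFD_p53KO 6. Of 50 genes eligible for naming and past the threshold here, 49 kept their direction, the exception being Sult1e1, and 27 passed in each of 13 fits with 1 library left out, among them Plin4, Plin2, Gm2a, Herc6, Eda2r, Sesn2 and Abhd4. Acacb passed in 12 of the 13, Acly in 11, Acss2 in 10, Abcb4, Bmp2 and Hal in 8, Ddx58 and Xaf1 in 7, Pparg in 6, Igfbp2 in 5, Cps1 and Oasl2 in 4, Elovl6 and Fdps in 3 and Cyp3a16 (log2 fold change -1.73) in 2. Without the libraries high in neutrophil markers 40 of the 50 passed, and those that did not included Cpt1a (log2 fold change 0.66 with all libraries, 0.44 without these), Ddx58 (0.75, 0.64), Xaf1 (1.16, 0.999), Oasl2 (2.16, 2.01) and Reln (-1.06, -0.89). Over all genes 246 of the 405 calls stood in that fit. Without the libraries high in acute phase genes 214 of the 405 stood, and with surrogate variables 271.

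Camera placed 5 lists higher and 7 lower on HFD in p53KO. Interferon-stimulated genes were higher (median log2 fold change 1.14, 38 of 38 above 0, adjusted p 6.42e-26, with an estimated correlation 0.283), 7 over all genes, among them Herc6, Ddx58 (0.75), Xaf1 (1.16) and Oasl2 (2.16), and 32 adjusted over the list alone. Lipid droplet genes (0.62, 18 of 20 above 0, 2.99e-08, with an estimated correlation 0.283) had 3 over all genes and 8 adjusted over the list alone. The p53 target genes (0.26, 36 of 43 above 0, 6.57e-07, with an estimated correlation 0.283) had 4 over all genes, and 11 higher and 1 lower adjusted over the list alone. Fatty acid oxidation genes (0.52, 29 of 30 above 0, 2.92e-11, with an estimated correlation 0.480) had 3 over all genes, Cpt1a (0.66), Pex11a (1.09) and Slc25a20 (0.70), and 11 adjusted over the list alone. None of these 3 passed without the libraries high in neutrophil markers (adjusted p 0.119, 0.0722 and 0.0989), where their log2 fold changes were still positive (0.44, 0.87 and 0.51). With 1 library left out they passed in 6, 3 and 2 of 13 fits. Targets of NRF2, a regulator of antioxidant genes, were higher (0.19, 14 of 19 above 0, 0.00282, with an estimated correlation 0.450), with Nqo1 (1.41) and Srxn1 (1.5) past the threshold and 5 higher and 1 lower adjusted over the list alone. By fry, which asks whether a list moves 1 way, the interferon-stimulated, p53 target and lipid droplet genes had an adjusted p of 0.0143 and the NRF2 targets 0.0370, and this directional test made no other call in any comparison. Its mixed test, for change in either direction, called 6 lists for HFD in Rosa26KO, 11 for HFD in p53KO and 0 in the other comparisons. The HFD rise of the p53 targets was thus measured in the knockout, and its difference from Rosa26KO in list score was 0.032 (SE 0.193, two-sided exact permutation p 0.884).

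Lists lower on HFD in p53KO were cholesterol synthesis (median log2 fold change -0.52, 24 of 25 below 0, adjusted p 2.92e-11, with an estimated correlation 0.534), with 4 over all genes, among them Pmvk (-1.17), Fdps (-1.07) and Stard4 (-0.97), and 12 adjusted over the list alone, and fatty acid synthesis (-0.63, 18 of 21 below 0, 3.01e-05, with an estimated correlation 0.599), with 5 over all genes, among them Acly (-1.29), Acacb (-1.29), Acss2 (-1.34) and Elovl6 (-1.36), and 10 adjusted over the list alone. Gluconeogenesis and insulin response genes (-0.29, 0.0115), with Igfbp1 and Igfbp2 (-1.83) past the threshold, periportal genes (-0.63, 0.00190), with Hal (-1.25) and Cps1 (-1.03), sinusoidal endothelial markers (-0.50, 1.87e-05), with Bmp2 (-0.70), stellate markers (-0.35, 0.00244), with Reln (-1.06), and neutrophil markers (-2.73, 0.0115) were also lower. With an estimated correlation their adjusted p was 0.589 or above. Adjusted over the list alone, 3 gluconeogenesis genes, 7 periportal genes with 1 higher, 3 endothelial, 3 stellate and 8 neutrophil markers were lower. Of the 12 lists, 9 moved in list score by less than 1.5 times whichever single library was left out. The score difference went from -1.19 to -0.44 for neutrophil markers without Control_p53KO 1, and from -0.37 to -0.17 for stellate markers and from -0.43 to -0.26 for endothelial markers without HFD_p53KO 7. Without both Control_p53KO 1 and 3 it reversed for neutrophil markers (0.13), and went from 0.69 to 0.40 for fatty acid oxidation, from -0.61 to -0.96 for fatty acid synthesis and from 0.30 to 0.45 for NRF2 target genes. Female-biased genes were not called, and their median (-0.62) and test (higher) differed in sign. In Rosa26KO stellate, acute phase and B cell lists, also not called, differed in sign as well.

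Whether HFD acted alike in both genotypes was asked by setting the effects side by side over 14133 genes. Genes past the threshold in both genotypes moved the same way, with 0 in opposite directions by edgeR. Of these, 22 rose in both and 49 fell in both, where 1.02 and 1.87 were expected if calls fell on genes independently. Both sets of calls came from 1 fit that shares each gene's estimate of spread. Such calls are not independent, so the expected numbers are no test against chance. Of the 213 genes of Rosa26KO, 202 had the same sign in p53KO, and of the 405 genes of p53KO, 377 had the same sign in Rosa26KO. Across genes the log2 fold changes correlated with a Pearson r of 0.317 and a Spearman rho of 0.282, and a jackknife over libraries gave the r an SE of 0.349, with values from 0.206 without Control_p53KO 5 to 0.462 without Control_p53KO 1. The genotype effects on control diet and on HFD correlated with r -0.244 and rho -0.194 (SE of r 0.293). Genes are not independent replicates, both diet effects share no library, and both r lay within their jackknife SE of 0.

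**Figure D3:**
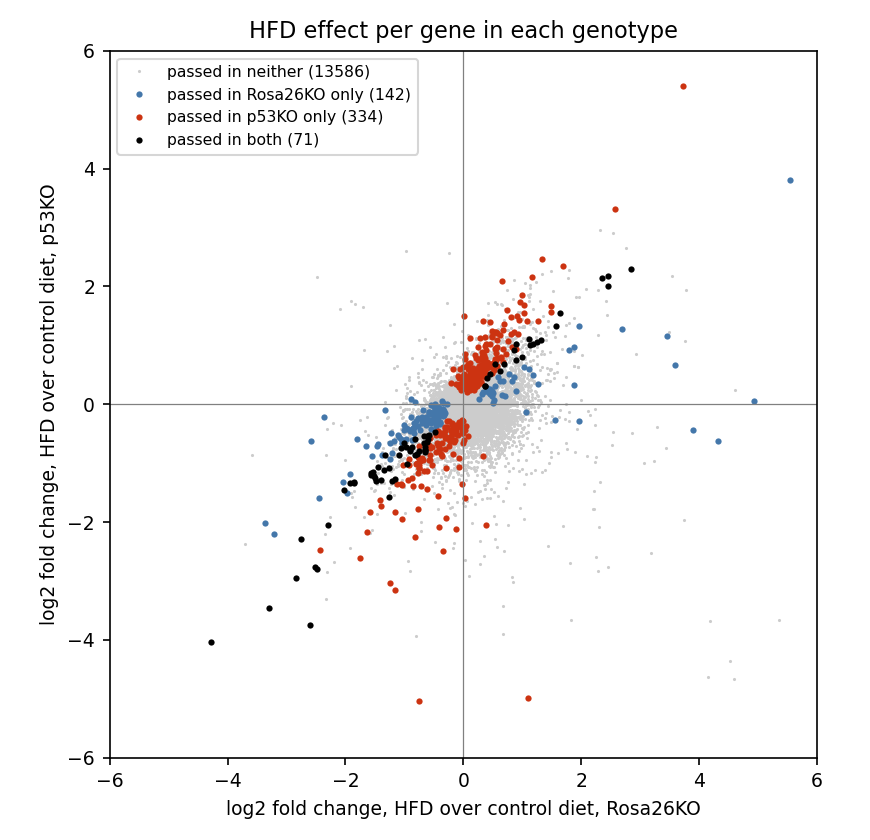
The log2 fold change of HFD over control diet in Rosa26KO (horizontal axis) and p53KO (vertical axis) for each of 14133 genes, coloured by the genotype in which edgeR called it. Genes called in both genotypes lie in the same direction, 22 up and 49 down.

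Whether the HFD effect differed between genotypes was asked by the interaction. By edgeR 0 genes passed, with 1221 at an unadjusted p under 0.05 and a smallest adjusted p of 0.462. Other splits gave a median of 548 at an unadjusted p under 0.05, and 12 of 100 gave at least 1221. DESeq2 called 5 (1330 unadjusted) and limma voom 0 (924 unadjusted). Rogdi (0.64) and the zinc finger gene Zfp64 (0.64) had positive interaction values, and by DESeq2 their adjusted p was 0.0112 and 0.0173. Rogdi was at 16.1 ± 1.5 CPM (SD, n = 6) in Control_Rosa26KO, 15.6 ± 1.53 (SD, n = 6) in HFD_Rosa26KO, 12.3 ± 1.46 (SD, n = 6) in Control_p53KO and 18.5 ± 2.22 (SD, n = 7) in HFD_p53KO. The neutrophil granule genes Mpo (-9.02), Ngp (-9.26), Camp (-8.88) and Ltf (-8.77) had the largest negative values among the 10 genes of smallest p, and DESeq2 called Mpo, Ngp and Ltf. They rest on single libraries, with Mpo at 38.7 CPM in Control_p53KO 1 and 49.8 CPM in HFD_Rosa26KO 6, and Ngp at 137.6 and 109.7 CPM. Usp10 (0.57), Fzr1 (0.40), Nrbp1 (0.33) and Chsy3 (-1.06) completed the genes of smallest p. Camera placed 6 lists higher and 10 lower for the interaction, and with an estimated correlation no call held (adjusted p 0.700 for each).

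**Figure D4:**
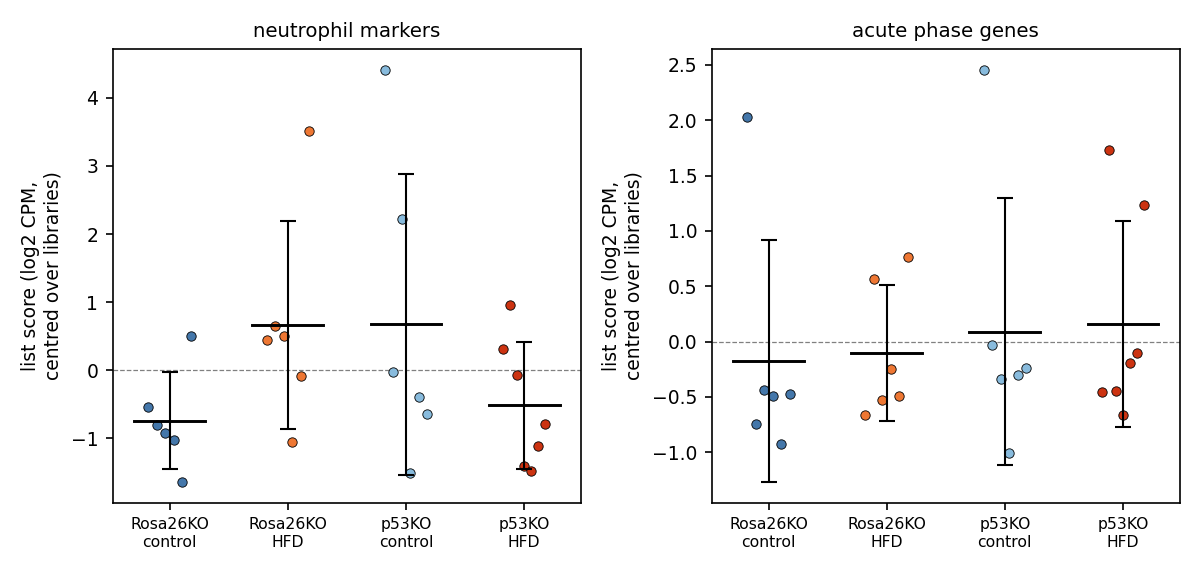
Scores of the neutrophil markers and of the acute phase genes (mean log2 CPM of the members, centred over the 25 libraries) in each library of the 4 groups. Control_p53KO 1 (4.41), HFD_Rosa26KO 6 (3.51) and Control_p53KO 3 (2.21) lie apart in the neutrophil markers.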

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

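The tests of a wrong diet label, of blood cell formation and of blood measured without Prtn3, and the list scores with libraries left out, were chosen only after the result was seen. Values of 109 genes, 34 lists and the library totals were compared within each group of 6 or 7 libraries, 576 groups of values in all, by the gap of the extreme library to its neighbour as a share of the range. Chance alone puts about 1 in 20 such groups past the published bound for its size, and 47 passed. They gathered in a few libraries: 11 in Control_Rosa26KO 2, 10 in HFD_Rosa26KO 6, 6 in Control_p53KO 3, 7 in HFD_p53KO 7 and 4 in Control_p53KO 1.

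Control_Rosa26KO 2 was the highest of its group in 8 genes and 3 list scores. The gap was 0.694 of the range for Abhd4, 0.681 for Aen, 0.674 for Fam110a, 0.663 for Oasl2, 0.632 for Spats2l, 0.756 for Sprr1a, 0.706 for Cyp3a41a and 0.685 for Cyp3a41b. It was also the highest in the scores of p53 target genes (0.701), cell cycle genes (0.685) and extracellular matrix genes (0.672). These are genes that HFD raised in p53KO or lists that camera placed higher on HFD in Rosa26KO, apart from Aen, Fam110a, Cyp3a41a and Cyp3a41b. No explanation was tested for this library.

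HFD_Rosa26KO 6 was the lowest of its group in single genes, with gaps of 0.730 for Cbr3, 0.801 for Nqo1, 0.718 for Srxn1, 0.686 for Plin2, 0.853 for Pparg and 0.651 for Rad51b, and in the scores of lipid droplet genes (0.627) and DNA repair genes (0.638). It was the highest in the granule genes Mpo (0.695) and Ngp (0.647). Control_p53KO 1 was the highest in Sult1e1 (0.734), Egln1 (0.771) and the acute phase score (0.718), and the lowest in Cyp4a12b (0.873). Control_Rosa26KO 1 was the highest in the acute phase score (0.837) and the lowest in the xenobiotic metabolism score (0.631).

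Control_p53KO 3 was the lowest in Commd3 (0.732), the periportal enzyme gene Hal (0.812), Tm7sf2 (0.711) and the gluconeogenesis score (0.714), and the highest in the scores of Kupffer cell markers (0.703) and of T and NK cell markers (0.626). HFD_p53KO 7 was the lowest in Colec10 (0.604), Cyp2b13 (0.586), Slc22a27 (0.652) and the stellate cell score (0.669), and the highest in Efna3 (0.576), Endog (0.577) and the male-biased score (0.581). Single values stood apart for Aen (0.695) and Trp53cor1 (0.612), lowest in HFD_p53KO 5, for Slc22a27 (0.804), lowest in Control_Rosa26KO 6, for Slc25a1 (0.640), highest in Control_Rosa26KO 5, for Stab2 (0.716), lowest in Control_Rosa26KO 5, for Slc7a4 (0.651), lowest in HFD_Rosa26KO 4, and for Pdcd10 (0.569), lowest in HFD_p53KO 2.

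HFD effects of 16 lists differed between the genotypes by camera with a preset correlation, and none with an estimated correlation (adjusted p 0.700 for each). Higher in p53KO were interferon-stimulated genes (adjusted p 0.00163, median interaction 0.40), xenobiotic metabolism genes (0.00163, 0.32), male-biased liver genes (0.000268, 0.72), pericentral genes (0.0129, 0.27), fatty acid oxidation genes (0.0316, 0.20) and cholesterol synthesis genes (0.0495, 0.28). Lower in p53KO were cell cycle genes (8.45e-07, -0.58), neutrophil markers (4.12e-06, -4.81), sinusoidal endothelial markers (4.41e-05, -0.41), Kupffer cell markers (0.000524, -1.01), hepatic stellate cell markers (0.00322, -0.39), extracellular matrix genes (0.00362, -0.27), erythroid markers (0.0123, -1.65), macrophage markers (0.0167, -0.48), T and NK cell markers (0.0200, -0.53) and female-biased genes (0.0275, -1.19). Of 100 splits within diet, 39 gave as many list calls as the 16 found, and the highest other gave 24. Chance could therefore not be excluded for this number of calls. Control_p53KO 1 and 3 and HFD_Rosa26KO 6, high in neutrophil markers, carried much of these list interactions together. Without all 3 the score interaction went from -2.59 to -0.70 for neutrophil, from -0.83 to -0.31 for cell cycle and from 0.27 to 0.11 for pericentral genes, which no single library moved by 1.5 times. It reversed for macrophage markers (0.04) and fatty acid oxidation genes (-0.26), and was 0.02 for xenobiotic, -0.19 for erythroid, -0.11 for T and NK cell, -0.27 for Kupffer, -0.17 for matrix, 0.101 for cholesterol synthesis and 0.74 for male-biased genes. The interaction of interferon-stimulated genes went from 0.38 to 0.13 without Control_Rosa26KO 2, 0.25 without Control_p53KO 2 and 0.22 without Control_p53KO 5. Without HFD_p53KO 7 it went from -0.44 to -0.24 for stellate, from -0.50 to -0.33 for endothelial, from -0.48 to -0.22 for matrix, from -0.51 to -0.27 for macrophage, from -0.52 to -0.34 for T and NK cell and from -0.68 to -0.39 for female-biased genes. Without Control_p53KO 3 it was -0.18 for T and NK cell, -0.25 for macrophage and -0.44 for Kupffer markers (-0.72 with all), and without Control_Rosa26KO 5 -0.31 for macrophage and -0.47 for Kupffer markers. Without Control_p53KO 1 it went from 1.11 to 0.61 for male-biased genes and to -0.38 for female-biased genes, which were at -0.34 without Control_p53KO 4. Without HFD_Rosa26KO 6 it went from 0.44 to 0.26 for xenobiotic genes and from -1.14 to -0.67 for erythroid markers. For cholesterol synthesis (0.21) it was 0.05 without Control_p53KO 3, 0.06 without HFD_p53KO 5, 0.07 without HFD_p53KO 7, 0.13 without HFD_Rosa26KO 5 and 0.12 without Control_Rosa26KO 4, and for fatty acid oxidation (0.14) 9 libraries moved it, from -0.06 without Control_p53KO 1 to 0.34 without Control_p53KO 4.

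The neutrophil granule transcripts of Control_p53KO 1 and HFD_Rosa26KO 6 were weighed against blood left in the tissue. A test on Elane, Prtn3 and Ctsg, which circulating neutrophils have largely switched off, gave 73.7 CPM in the lower of both libraries and decided nothing, because Prtn3 alone reached 101.7 CPM in another library. Without Prtn3 the lower value was 18.9 CPM, against at most 2.63 CPM in the other 23 libraries, which argues against normal circulating blood as the only source. Blood cell formation in the liver stays open in both libraries, since 1 of 3 other kinds of blood cell transcripts was highest of its group in each. In Control_p53KO 1 globins were highest (1864 CPM, 622.5 to 1104 in the other 5 libraries), while erythroid transcripts were lowest (42.5 CPM, 67.98 to 104.8) and megakaryocyte ones lay within the range (9.95 CPM, 4.14 to 60.2). In HFD_Rosa26KO 6 megakaryocyte transcripts were highest (196.8 CPM, at most 19.4 in its group), and erythroid ones (165.4 CPM) and globins (5945 CPM) came after HFD_Rosa26KO 1 (168.7 and 8085 CPM). Immature neutrophils from another source stay open in both, and no biological explanation from the design was tested.

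HFD_p53KO 7 lay with control-diet libraries on the first component, and a wrong diet label may be the reason. Over the genes that HFD moved in Rosa26KO its score was 0.0253, within the range of Control_p53KO (-0.531 to 0.0757) and below the other 6 HFD_p53KO libraries (0.196 to 0.439). The upper end of that range came from Control_p53KO 1 and 3, and the highest of the other control libraries was -0.297, so the score was intermediate. On 35 of these genes that separated the diets in the other p53KO libraries, it lay nearer to the HFD mean for 48.6%, against 0 to 48.9% for control libraries held out in turn and 67.9% or more for HFD libraries held out. The upper end again came from part of the control libraries. Control_p53KO 1, 3 and 4 lay at 39.2%, 46.6% and 48.9%, and Control_p53KO 2, 5 and 6 at 0%, 2.78% and 5.56%. Single genes went with the label of HFD_p53KO 7, with Gm2a at 108.3 CPM (194.5 to 248.2 in Control_p53KO) and Plin4 at 42.8 CPM (at most 22.7), both chosen after their values were seen, and a weaker response of this mouse to HFD stays open as well.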

How the results depend on the processing

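The settings without the libraries high in neutrophil markers or in acute phase genes, with library runs or surrogate variables as terms, with exact list scores, with a trended variance in camera, and with libraries left out for single named genes, list scores or the exact tests of Trp53, Cdkn1a and Mdm2 were chosen after seeing the data. RLE scaling, dispersion without the robust option and no filter kept each count of changed genes within 1.5 times its reported value. Of 432 values of named genes, 85 past the threshold, RLE kept 85 calls, DESeq2 85 (52 gained), voom 75 (54 gained), and no filter 73.

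HFD against control diet in Rosa26KO called 213 genes, and 615 with DESeq2, 3038 with voom, 442 with library runs, 538 without the libraries high in neutrophil markers, 385 with surrogate variables and 653 with only the compared groups in the fit. In p53KO it called 405 genes, and 907 with DESeq2, 2189 with voom, 633 with library runs, 803 with surrogate variables and 121 with only the compared groups. The calls with surrogate variables held 143 of the 213 genes in Rosa26KO and 271 of the 405 in p53KO. The cause was not tested. Single libraries left out gave 93 to 509 in Rosa26KO and 173 to 760 in p53KO, from fewer samples.

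Where edgeR called 0 genes, DESeq2 called 1 on control diet, 1 on HFD, 7 for the average and 5 for the interaction, and voom called 2 for the average. Surrogate variables gave 1 on control diet (Trp53, -0.84), 2 on HFD (Acot13, -0.37, and Efna3, -1.31, chosen after their values were seen) and 2 for the average (Trp53 and Efna3). Without the libraries high in neutrophil markers the average had 1 (Trp53, -0.65). Single libraries left out gave 0 to 1 for the average and 0 for the other genotype comparisons and the interaction. The cause was not tested.

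The labels do not say whether replicate numbers pair samples. Of 36 pairs of libraries with the same number, 17 correlated above 0.1 (mean 0.116, other pairs -0.022), and 9 of 25 libraries were closest to one with their own number. Clock gene phase differed between runs of these numbers (two-sided exact permutation p 0.00014, a test chosen after the result was seen). Libraries of a run thus shared some structure, while a pairing of samples by single number stays open. The number was left out of the reported values by a choice fixed before the data were examined, because the labels state no pairing. With the replicate block the counts were 549 in Rosa26KO, 785 in p53KO and 1 for the average (Trp53). The block kept 75 of the 85 calls of named genes and gained 24. Of the calls it ended, 4 were for HFD in Rosa26KO and 6 for HFD in p53KO. The cause was not tested.

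Sult1e1 reversed on HFD in p53KO, from -4.98 to 1.4 without Control_p53KO 1 and 1.19 without the libraries high in neutrophil markers (-5.29 to 1.4 over all single libraries left out), because Control_p53KO 1 held its counts. With voom the value was 0.82, and the reason for that reversal was not tested. Of 87 camera calls of lists, RLE kept 86, the block 76 (14 gained) and a trended variance 87 (1 gained), while 0 stood with an estimated correlation, 4 with fry and 0 with exact list scores. With 6 against 6 libraries a list standing alone could not pass with exact scores. Its adjusted p can reach no lower than 0.0736, so these scores cannot decide such a case. For HFD in Rosa26KO the smallest adjusted p by exact list scores equalled this bound (0.0736). The estimated correlation counts the joint movement of a list's genes between libraries as noise. With 1 library left out, the list score difference reversed for oxidative phosphorylation between genotypes on HFD (-0.114 to 0.003014) and for the interaction of fatty acid oxidation genes (-0.0612 to 0.336). Without the libraries high in neutrophil markers together it reversed between genotypes on control diet for cell cycle (0.427 to -0.111), fatty acid oxidation (-0.251 to 0.0397), male-biased (-0.581 to 0.0322) and macrophage genes (0.371 to -0.177), for neutrophil markers on HFD in p53KO (-1.19 to 0.127), and for the interactions of fatty acid oxidation (0.142 to -0.264) and macrophage genes (-0.514 to 0.0443). The diet agreement r of 0.317 was 0.534 with the block and 0.144 without a filter, within its jackknife SE of 0.349. With 6 or 7 libraries per group and this spread, about 1.5-fold changes were found in only 44.8% to 58.2% of simulated cases.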

Other observations

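The clock, p53 target and library run tests of this part were chosen only after the result was seen, and the splits of the samples were planned. Rhythmic genes set the libraries apart by the run of library names. The clock output gene Dbp ran from 1.68 to 78.2 CPM over the 25 libraries. A phase score of clock genes was -1.26 ± 0.552 (SD, n = 8) in replicates 1 and 2 of the groups, 0.32 ± 0.752 (SD, n = 8) in replicates 3 and 4, and 0.84 ± 0.687 (SD, n = 9) in replicates 5 to 7. A candidate explanation is that livers of the runs were collected at different times of day. The score differed between runs within groups (two-sided exact permutation p 0.00014), and runs held 66.7% of its variance within groups. No other fixed list reached as large a share (0 of 34, the largest 48.9% for the circadian clock list itself). The phase score sets genes of later phase against genes of earlier phase, while list scores are plain means. Genes that move in opposite directions cancel in such means, so this comparison does not show that clock genes stand out. Each run holds libraries of all 4 groups, so no group lies in 1 run alone. When livers were collected within a run is not given and may differ between groups. Group means of the score ran from -0.48 ± 1.10 (SD, n = 6) in Control_Rosa26KO to 0.57 ± 1.23 (SD, n = 7) in HFD_p53KO and were not tested against each other.

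Eda2r, Sesn2 and Abhd4, known targets of p53, rose on HFD in livers in which Trp53 was knocked out. If this rise needed Trp53, the list score should change less in p53KO. It changed by 0.34 in Rosa26KO and 0.38 in p53KO, a difference of 0.032 (SE 0.193, exact permutation p 0.884), which cannot be told apart from either outcome because the spread between libraries is wide and Trp53 transcript remained at means of 24.1 and 26.1 CPM in p53KO. Other regulators of these genes, or p53 in cells that kept it, may contribute, and neither was tested.

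Splits of the same libraries into other groups of the same sizes were fitted, 100 for each comparison with the real one. For HFD in Rosa26KO 1 split (the real one) gave as many as 213 genes, and the highest other gave 2. That made chance an unlikely reason for the 213 genes. With 100 splits a share under 1 in 100 cannot be seen, so chance was not excluded. For HFD in p53KO 2 splits, the real one included, gave as many as 405 genes. Chance was thus an unlikely reason for this count but was not excluded. The highest other gave 1929, with Control_p53KO 2, 4 and 5 and HFD_p53KO 2, 5, 6 and 7 together, which points to a structure of the samples other than diet. For the genotype comparisons and the interaction, with 0 genes each, 100 of 100 splits necessarily gave as many, so these splits say nothing about chance. The highest other gave 375 on control diet, 1 on HFD, 5 for the average and 1 for the interaction. The split with 375 put Control_Rosa26KO 2 and 6 with Control_p53KO 1, 2, 3 and 6, also a structure other than genotype.

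For the number of lists called by camera chance could not be excluded in any comparison. The splits counted calls and did not follow which lists were called, so they cannot judge a single list. On control diet 39 splits gave as many as the 15 real calls (highest other 23), on HFD 66 as many as 15 (26), for the average 72 as many as 12 (24), for HFD in Rosa26KO 22 as many as 17 (21), and for HFD in p53KO 85 as many as 12 (23).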
